A study of Mus musculus with 18 samples.

How the data were processed

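ATAC-seq libraries were made from 10000 sorted lung epithelial cells each, with the protocol of Corces and colleagues, per the labels' protocols. Reads were handled with FastQC, Bowtie2 and MACS2 against the mouse build mm10, per the submitters' processing notes, which give no versions or settings in the sources used here; read shifting for the transposase, duplicate removal and the peak threshold are not given in the sources used here. Each deposited file was a list of peak intervals with a peak name and a score. Peak names carry a library name and the letters NFR, read here as nucleosome-free regions, so peaks were called per library and not on pooled libraries, per the names in the files. The score column holds the authors' peak score, as deposited; its scale is not given in the sources used here, and it was used only to rank peaks within a list. No read counts or depths come with the lists, so the depth of each library is unknown. The highest peak number in each list served as a lower bound on the peaks called, since numbers rose along each chromosome in all 10 libraries.

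The lists turned out to be treatment-specific subsets of the called peaks, as the overlaps show: replicate lists overlapped almost fully and opposite arms almost not at all. The way in which the subsets were made is not given in the sources used here. A list selected against its replicate and against the other arm cannot show how much replicates differ, and a peak present in both arms is absent from it. Repeated lines, 47 to 472 per file (1.23% to 6.01% of lines), were dropped. Groups were taken from the sample labels and replicate numbers from the titles. The design text names separate mice; a replicate number shared by the arms does not pair mice, and the sources used here do not tie library numbers of different populations to a mouse.

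Regions were the union of the peaks of the libraries compared, merged where they overlapped by at least 1 bp. A region was G9ai-only when it had a peak in every G9ai library and in no vehicle library of that population, and vehicle-only in the opposite case. Population-specific regions within an arm were defined the same way between populations. List lengths and covered lengths were compared by exact permutation of the arm labels, two-sided, and within populations for the test over all 3. Agreement between lists was the Jaccard index by bases, with 100000 permutations of the group labels.

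Genes came from a RefSeq table of assembly GRCm38.p6, the same build as mm10, with 21883 protein-coding genes. The table gives gene spans without strand or exons, so transcription start sites, promoters, exons and introns were not used here; the planned promoter windows were replaced, before any gene result was computed, by the gene span and 1000 bp on either side, with 1000 bp around either gene end as an alternative. A region in the window of several genes was assigned to each. Motif content was not analysed here, since no genome sequence was used. Of 439 names in 20 gene lists fixed before the data were examined, 437 matched a protein-coding gene. The lists covered lung cell types, other cell types the gate could hold, the sort markers and gene classes linked to H3K9 methylation, and several airway and alveolar genes are active in more than 1 of these cell types.

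List members were tested against other genes with a two-sided Fisher exact test, adjusted by Benjamini-Hochberg over 100 tests, where every group had 2 libraries. Where a group had 1 library, the number of list genes on the G9ai side was given its percentile among 10000 random lists of the same size from the genes with a region, without a p. The number of list genes with a region was also set against 10000 random lists drawn from 20 bins of gene length; this description and the comparison of directions between populations were chosen after the data were seen. Percentiles use mid-ranks. Odds ratios are conditional maximum likelihood estimates with exact 95% intervals. Genes in a list are not independent samples of mice, and these tests describe the lists of these libraries.

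Named genes followed a rule set before the data were examined: 12 genes always named in the report, and per region set up to 10 list genes and up to 10 other genes whose regions lay in 1 arm only, in the order of the mean score of the best peak per library, leaving out Gm, Rik and Olfr symbols; the gene link above took the place of promoters in it. Some genes that the rule selects are not reported here. Genes named as examples of a list were chosen after their regions were seen. The same rule was used between populations within G9ai. Random and planted lists were also scored on the CD24low regions. Of random lists of 25 genes, 9 of 200 fell outside the central 95% of length-matched draws. Planted lists of 30, with 12 members on G9ai-only genes, lay above it in 50 of 50 cases. The Fisher test called 14 of 200 random lists of 10 genes at an unadjusted p under 0.05. It also called 50 of 50 lists of 10 with 8 members placed off the G9ai side. Weaker effects, smaller lists and the adjusted threshold were not tried, so the power of the adjusted tests is unknown. With shuffled arm labels the interval of the direction odds ratio held 1 in 97 of 100 cases for CD24neg and CD24low.

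Alternatives were the higher-scoring 50% of each list, equal list lengths, presence only where peaks cover at least 50% of a region, peaks of a fixed 200 bp, a common score minimum of 41, other gene windows, another gene background, autosomes only, leaving out each replicate and a replicate block. For equal list lengths, region and gene counts used the length of the shortest list of the population compared. Population-specific regions used that of the shortest G9ai list. List tests, list percentiles and directions used the 2552 peaks of the shortest list of all. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used.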

Results

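Chromatin accessibility was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in epithelial cells of the adult mouse lung (C57BL/6, 6 to 12 weeks old). Cells negative for CD31 and CD45 and positive for Epcam and Sca-1 were sorted by their CD24 level into CD24-negative (CD24neg), CD24low and CD24high populations. Mice received an inhibitor of G9a (G9ai), the methyltransferase encoded by Ehmt2 that places methyl groups on lysine 9 of histone H3, or vehicle. The design had 3 mice per arm and 10000 cells per library, giving 18 samples in 6 groups. Peak lists of 10 libraries were analysed: G9ai replicates 2 and 3 of every population, vehicle replicates 2 and 3 of CD24low, and vehicle replicate 3 of CD24neg and of CD24high. The other 8 samples were not analysed here. CD24low was therefore the population with replicates in both arms, and differences in CD24neg and CD24high have no replicate check on the vehicle side.

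The lists held between 2552 peaks (CD24low vehicle replicate 3) and 12985 peaks (CD24high vehicle replicate 3), with median widths of 129 to 183 bp. Each was a small part of the peaks called in its library. The highest peak number in a list, a lower bound on the peaks called, ran from 60603 to 98001, and the listed peaks made up 3.03% to 13.2% of that number. Of the peaks in a list, 98.2% to 99.6% overlapped a peak of the other library of the same group, while only 10 to 102 peaks per list overlapped a list of the opposite arm in the same population. Lists of the same group shared a mean Jaccard index by bases of 0.6 (range 0.572 to 0.632 over 4 pairs), against 0.0188 between groups (one-sided permutation p = 0.00027, 100000 permutations, 10 libraries). Agreement of replicates and absence from the opposite arm were thus properties of the lists as deposited, and the spread between replicate lists understates the error between mice. At most 0.177% of peaks had identical coordinates in replicate lists, so no library was counted as a copy of another. A gene or region without a listed peak may be open in both arms.

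**Figure D1:**
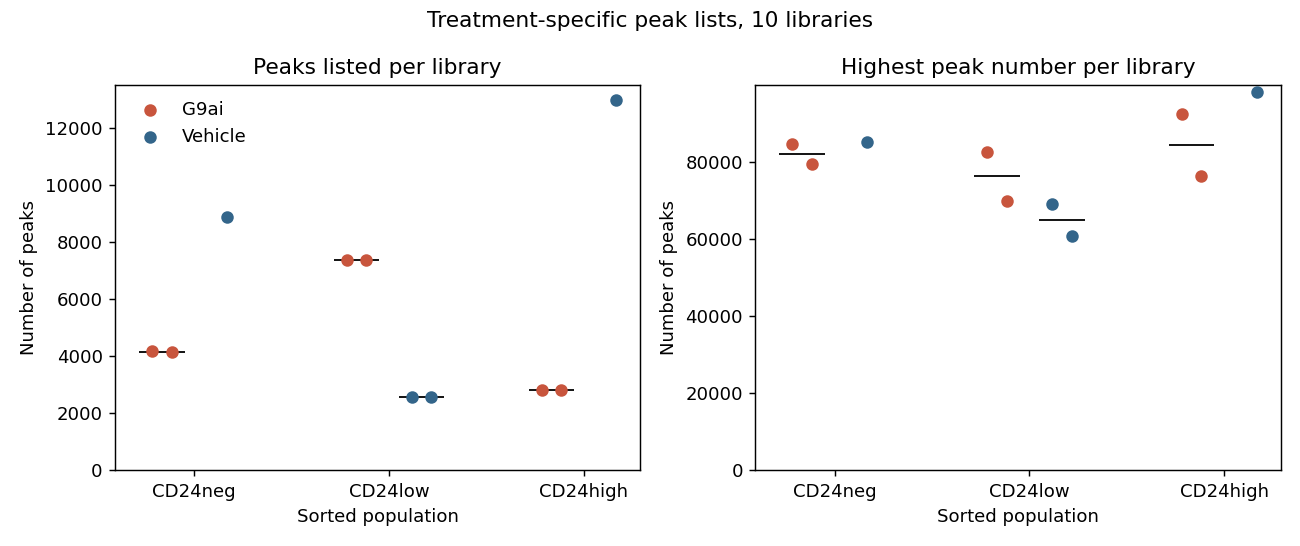
Peaks listed per library (left) and the highest peak number in each list (right, a lower bound on the peaks called), by sorted population; points are libraries, horizontal lines the means of 2 libraries, red G9ai and blue vehicle. G9ai lists were longer than vehicle lists in CD24low (means 7370 and 2555) and shorter in CD24neg (4161 and 8870) and CD24high (2807.5 and 12985).

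The first comparison set the regions listed with G9a inhibition in CD24low cells against those listed with vehicle. Regions found only with the inhibitor lay in 10 of 24 genes of club cells, the secretory cells of the airway (3.25 expected from gene length), and regions found only with vehicle in 4 (1.59 expected); the share of club-linked regions on the G9ai side, 77.8%, was near the 73.1% of all gene-linked regions. The 10 genes included Scgb1a1, Scgb3a1 and Scgb3a2, which encode abundant airway secretory proteins, the cytochromes P450 Cyp2f2 and Cyp4b1, the retinaldehyde dehydrogenase gene Aldh1a1 and Pigr, whose product carries immunoglobulin A across epithelia. Regions found only with vehicle lay in 4 genes of a list of H3K9 and DNA methylation factors: Ehmt2 itself, the demethylase gene Kdm3b, the chromodomain gene Cdyl and the maintenance DNA methyltransferase gene Dnmt1. That is 4 of 25 genes of the list, where lists of the same gene lengths had 2.70 (percentile 80.4), and 3 others of the list, Atf7ip, Cbx5 and Dnmt3a, held G9ai-only regions. In all, 7172 regions had a peak in both G9ai libraries and in no vehicle library (G9ai-only), and 2500 had the opposite pattern (vehicle-only), with 18 regions seen in both arms.

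The Scgb1a1 region lay on chromosome 19 at 9087796 to 9088263 (mm10), across the higher-coordinate end of the gene span (9083642 to 9087956). Kcnk2, a potassium channel gene of the club list, held 3 G9ai-only regions, the one with the highest score at 189370147 to 189370462 on chromosome 1, inside the gene. The Pigr region lay inside its gene on chromosome 1 at 130832212 to 130832672. Pax6, a developmental transcription factor gene, held a G9ai-only region at 105674556 to 105674762 on chromosome 2, and Ifit3, an interferon-induced gene, one at 34586239 to 34586367 on chromosome 19. Outside the lists, the genes whose G9ai-only regions had the highest mean scores were Pdcl3, which encodes a phosducin-like protein, and Hey2, a transcription factor gene activated by Notch (30842698 to 30843438 on chromosome 10). Next came a region shared by the neighbours Pqbp1 and Timm17b on chromosome X, then Fuca2 (a fucosidase), Rbx1 (a ubiquitin ligase subunit), Usp53, Psmd3 (a proteasome subunit), Fto (an RNA demethylase, 5 regions) and Hnrnpf (an RNA-binding protein).

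On the vehicle side, Ehmt2 held 2 regions, the stronger at 34912191 to 34912316 on chromosome 17, inside the gene and 1757 bp from its nearer end. Kdm3b also held 2 regions, the stronger at 34776840 to 34776988 on chromosome 18, ending 19 bp outside the lower-coordinate end of the gene. Other list genes with vehicle-only regions were Spock2 (alveolar type 1 list), Chad and Nupr1 (club list), Fcer1g (an Fc receptor subunit of immune cells), Syp (synaptophysin), Polr2a (the largest subunit of RNA polymerase II) and the Notch ligand gene Jag1. Sftpc, which encodes the surfactant protein C of alveolar type 2 cells, had 1 vehicle-only region 413 bp outside its lower-coordinate end. Outside the lists the highest mean scores belonged to Sde2, the neighbours Cox4i1 (a subunit of cytochrome c oxidase) and Emc8, Erlin2, Fem1c, Cldn34d, Hacd3, Ppa1 (an inorganic pyrophosphatase), and the neighbours Adat3 and Scamp4.

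G9ai lists of CD24low held 7370 ± 12.7 peaks (SD, n = 2) and vehicle lists 2555 ± 4.24 (SD, n = 2), a ratio of 2.88 (log2 1.53). The covered length differed 3.60-fold (log2 1.85). Both gave p = 0.333 in a two-sided exact permutation test, which is the smallest p that 2 against 2 libraries allow. Regions within 1000 bp of either end of a protein-coding gene made up 16.9% of the G9ai-only regions (95% Wilson interval 16.1% to 17.8%) and 24.6% of the vehicle-only regions (23.0% to 26.3%). Per library that share was 16.9% ± 0.0571 (SD, n = 2) with G9ai and 24.4% ± 0.234 (SD, n = 2) with vehicle (exact permutation p = 0.333). Within gene spans and 1000 bp either side lay 63.7% and 67.4% of the regions. The share near gene ends ran the other way in CD24neg (18.2% of G9ai-only and 15.2% of vehicle-only regions) and CD24high (22.9% and 14.5%). In each population the arm with the shorter list had the higher share. With equal list lengths in CD24low, taking the 2552 peaks of highest score per library, regions defined anew numbered 1243 G9ai-only and 2503 vehicle-only. That cut left the vehicle lists almost whole and kept partly different peaks of the 2 G9ai lists, so it does not bear on direction.

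Of the 4505 genes with a CD24low region, 2878 had G9ai-only regions alone, 1016 vehicle-only regions alone and 611 both. No gene list was over-represented on either side after adjustment: over 100 Fisher exact tests, counting those within G9ai below, 0 had an adjusted p (Benjamini-Hochberg) under 0.05 and 1 an unadjusted p under 0.05. The lowest unadjusted Fisher exact p in CD24low was 0.05, for 4 of 7 H3K9 genes on the vehicle side (odds ratio 4.59, adjusted p = 1). Of 12 club genes with a region, 8 were on the G9ai side alone and 2 on the vehicle side alone (7.67 and 2.71 expected, both exact p = 1). Counted as regions, 14 club-linked regions were G9ai-only and 4 vehicle-only, or 77.8% against 73.1% of all gene-linked regions (Fisher exact p = 0.794). H3K9-linked regions numbered 3 and 6 (Fisher exact p = 0.0146, adjusted p = 0.195) and basal-linked regions 0 and 3 (Fisher exact p = 0.0195, adjusted p = 0.195). These region tests count several regions of 1 gene as independent, and the 6 vehicle-only H3K9 regions lay in 4 genes.

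A second description, chosen after the data were seen and after those tests had called no list, set the number of list genes with a region against 10000 random lists of the same gene lengths. The 10 club genes with a G9ai-only region lay at percentile 99.97 (96.4, inside the central 95%, when only 1000 bp around gene ends counted), and the 4 with a vehicle-only region (Chad, Cldn10, Nupr1 and Por) at percentile 95.9. None of the 16 basal-cell genes had a G9ai-only region (2.71 expected, percentile 2.39). Wnt, Notch and progenitor genes had vehicle-only regions in 7 of 30 cases (3.14 expected, percentile 98), including Bmi1, Jag1, Notch2 and Wnt7b. Of these 7 genes, 1 was left in the higher-scoring 50% of peaks (percentile 52.6). Notch2 also held G9ai-only regions. G9ai-only regions lay in 12 of 36 multiciliated-cell genes (7.93 expected, percentile 95.1), among them Foxj1, the regulator of motile ciliogenesis, and Mcidas. They also lay in 8 of 22 alveolar type 1 genes and 4 of 22 alveolar type 2 genes (5.35 and 3.62 expected). Germline genes, a class that G9a is known to silence, held G9ai-only regions in 2 of 22 cases, Sycp1 and Tex15 (4.14 expected, percentile 11.9), and imprinted genes in 5 of 21 (3.38 expected, percentile 83.9).

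Of the CD24low lists, only club and basal (G9ai-only regions) and Wnt, Notch and progenitor (vehicle-only regions) lay outside the central 95% of length-matched lists. G9ai-only regions fell in 10 of 30 Wnt, Notch and progenitor genes, 3 of 22 pan-epithelial, 3 of 25 H3K9, 4 of 23 interferon-response, 2 of 30 bivalent developmental, 2 of 22 cell-cycle and 5 of 30 housekeeping genes. Lists of other cell types gave 3 of 20 endothelial, 2 of 25 immune, 2 of 22 mesenchymal, 2 of 6 mesothelial and 2 of 14 neuroendocrine genes. Of the 5 genes of the sort itself, Pecam1 alone had a region. It encodes CD31, against which the cells were gated, and held 4 G9ai-only regions in CD24low, the one with the highest score at 106665409 to 106665612 on chromosome 11.

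**Figure D2:**
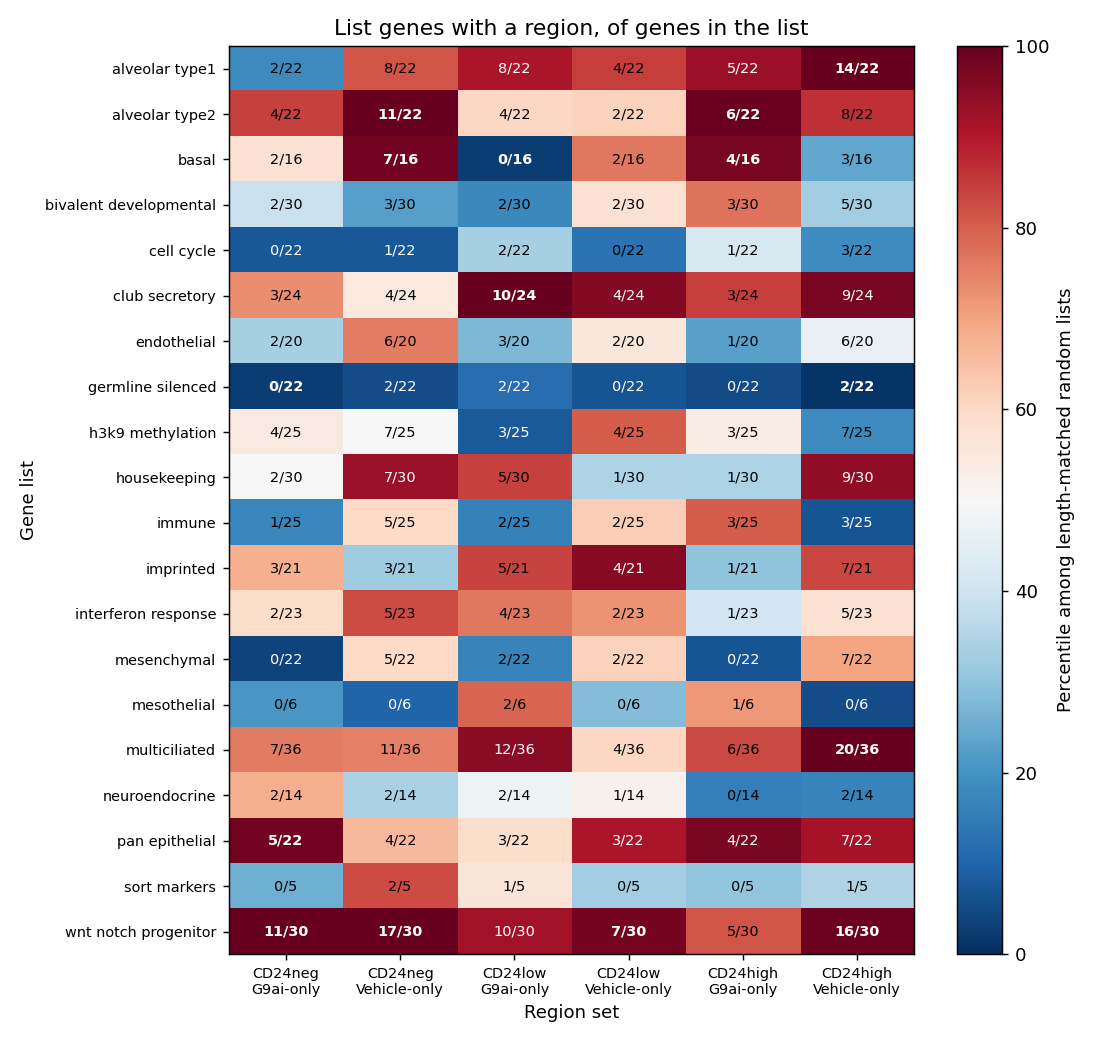
Genes of each list with a region in each of the 6 region sets (number of list genes with a region, of the genes in the list); colour is the percentile among 10000 random lists of matched gene length, and bold marks values outside the central 95%. The club list reached 10 of 24 in CD24low G9ai-only regions and the multiciliated list 20 of 36 in CD24high vehicle-only regions.

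In CD24neg cells the vehicle library carried the longer list, and its regions lay in genes of alveolar type 2 cells, the surfactant-producing cells of the alveolus. Vehicle-only regions fell in 11 of 22 such genes (4.40 expected, percentile 99.95), including the lipid transporter gene Abca3, the lamellar body gene Lamp3, the transcription factor gene Etv5, the protease gene Napsa and the lipid-remodelling enzyme gene Lpcat1. Lpcat1 was also among the genes with G9ai-only regions. The vehicle-only percentile was 36.6 near gene ends and 95.4 with equal list lengths, both inside the central 95%, but 100 in the higher-scoring 50% of peaks. Of 30 Wnt, Notch and progenitor genes, 17 held vehicle-only regions (8.05 expected, percentile 99.99) and 11 G9ai-only regions (4.58 expected, percentile 99.81), the latter including Sox2, Lgr5, Lgr6, Axin2 and Notch1. Of the 20 with a region, 3 were on the G9ai side alone and 9 on the vehicle side alone. The other 8, Axin2 and Notch1 among them, held both. Both percentiles fell inside the central 95% with equal list lengths (71.6 and 87.8) and in the higher-scoring 50% of peaks (85.9 and 85.6). Equal lengths here meant 2552 peaks in every library, a cut that shortened the G9ai lists as well. G9ai-only regions also lay in 5 of 22 pan-epithelial genes (1.80 expected, percentile 98.4): Cdh1, Ehf, Foxa2, Grhl2 and Krt18. Cdh1 and Grhl2 also held vehicle-only regions. The pan-epithelial percentile fell inside the central 95% with equal list lengths (86.9), in the higher-scoring 50% (92.9) and near gene ends (86.6).

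The Sox2 region, at 34649579 to 34650007 on chromosome 3, had the highest score among the G9ai-only list genes of CD24neg. It was followed by Ehf (an epithelial transcription factor), Krt18 (a keratin), Hydin (a component of motile cilia), Uhrf1 (which recruits the maintenance DNA methyltransferase), Ecscr, Lgr6, Rac2, Mcidas and Reep5. Outside the lists came Tprgl, Khdrbs1 (an RNA-binding protein), Dennd2c, Riok3, Dcp1a (an mRNA-decapping factor), Senp2 (a SUMO protease), Sema3b, Enoph1, Micos10 and Cdkl2. The strongest vehicle-only list region lay in Lamp3, at 19699125 to 19699634 on chromosome 16. Tek, Sec14l3, Spint2, Spi1, Lhx9, Aqp3, Cbx5, Abca3 and Vegfa followed. Outside the lists a region shared by the neighbours Ccdc146 and Fam185a on chromosome 5 had the highest score, followed by one near AY074887, Hykk and the proteasome gene Psma4, and by Psma3, Mrps9, Mark2 and Apbb3.

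The 2 G9ai lists of CD24neg held 4161 ± 17.0 peaks (SD, n = 2) and the vehicle list 8870, a ratio of 0.469 (log2 -1.09). G9ai-only regions numbered 4015 and vehicle-only regions 8783, with 86 in both arms; with equal list lengths, which bring the numbers together by construction, they were 4026 and 4095. Genes with G9ai-only regions alone numbered 1293, with vehicle-only regions alone 3100, and with both 1026. G9ai-only regions lay in 4 of 22 alveolar type 2 genes and 7 of 36 multiciliated genes (2.5 and 5.56 expected), and vehicle-only regions in 8 of 22 alveolar type 1, 11 of 36 multiciliated and 4 of 24 club genes (6.18, 9.31 and 3.85 expected), all inside the central 95%. The same held for both region sets in the H3K9 list (4 and 7 of 25), the imprinted list (3 and 3 of 21) and the interferon list (2 and 5 of 23), and for the bivalent, cell-cycle, housekeeping, sort-marker, endothelial, immune, mesenchymal, mesothelial and neuroendocrine lists. The basal-cell list had vehicle-only regions in 7 of 16 genes (3.38 expected, percentile 98.1), Trp63, the basal-cell master regulator, among them. Germline genes had no G9ai-only region in 22 genes (2.76 expected, percentile 2.37). Counted only within 1000 bp of a gene end, the alveolar type 2 list fell to percentile 36.6 and the basal list to 46.6 in vehicle-only regions. With every list cut to 2552 peaks they lay at 95.4 and 75.9. Among genes with a region in either arm, no list was outside the central 95% of random lists for the G9ai side.

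In CD24high cells the vehicle library again carried the longer list, and genes of lung cell types held regions of both arms. Of 36 multiciliated genes, 20 had a vehicle-only region (12.0 expected, percentile 99.8), among them Foxj1, the ciliary transcription factor genes Rfx2 and Rfx3, and the dynein genes Dnah5, Dnah9 and Dnaic1. That percentile was 41.95 near gene ends, but 99.4 in the higher-scoring 50% of peaks and 98.5 with equal list lengths. Alveolar type 1 genes, of the flat gas-exchange cells, had vehicle-only regions in 14 of 22 cases (7.94 expected, percentile 99.67), including Hopx, Cav1, Clic5 and Vegfa. The same lists held G9ai-only regions in 6 of 36 and 5 of 22 genes (4.16 and 2.64 expected). Rfx3, Dnah5, Dnah9 and Clic5 were among these genes and so held regions of both arms. Of multiciliated-linked regions 22.2% and of alveolar type 1-linked regions 12.8% were G9ai-only, against 18.3% of all gene-linked regions. G9ai-only regions lay in 6 of 22 alveolar type 2 genes (1.89 expected, percentile 99.58): Abca3, Cxcl15, Lgi3, Lpcat1, Ppp1r14c and Slc34a2. Vehicle-only regions lay in 8 genes of that list (5.79 expected, percentile 86.6), Abca3, Lgi3 and Ppp1r14c again among them, so 3 of the 11 with a region were on the G9ai side alone. G9ai-only regions also lay in 4 of 16 basal genes (1.38 expected, percentile 97.53), namely Aqp3, Bcl11b, Dlk2 and Itga6. Vehicle-only regions lay in 3 basal genes (4.24 expected), Aqp3 again among them. In the higher-scoring 50% of peaks the G9ai-only values of the alveolar type 2 and basal lists were 92.7 and 77.5, inside the central 95%, and the basal list also near gene ends (94.1) and with a window of 2000 bp (97.42).

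Among G9ai-only list genes of CD24high the highest mean score belonged to B2m, the light chain of class I histocompatibility molecules (122147437 to 122147986 on chromosome 2). It was followed by Lpcat1, Myb, Krt18, Cd79a, Gprc5a, Klf5 (an epithelial transcription factor, 3 regions), Cbx5 (heterochromatin protein 1 alpha), Rspo1 and Thbs1. Outside the lists came Gm2a (the GM2 ganglioside activator), the Pqbp1 and Timm17b region, Tiprl, Supt4a, Cyb5r4, Tgfbr1 (a TGF-beta receptor), Rab11fip3, Oacyl and Tsg101. Vehicle-only list genes were led by Lmo7 (alveolar type 1 list, 10 regions), with Rfx2, Col4a4, Sema3e, Tekt4, Grhl1, Gata4, Cyp2a5, Krt19 and Icam1 after it. Outside the lists Nutf2, Capsl, the neighbours Gmppb and Ip6k1, the neighbours Abce1 and Anapc10, Kif3a (a kinesin needed for cilia), the neighbours Psmc3ip and Retreg3, and Kctd16 had the highest scores.

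The 2 G9ai lists of CD24high held 2807.5 ± 13.4 peaks (SD, n = 2) and the vehicle list 12985, a ratio of 0.216 (log2 -2.21). There were 2675 G9ai-only and 12880 vehicle-only regions, with 105 in both arms; with equal list lengths, which bring the numbers together by construction, they were 2736 and 2773. Genes with G9ai-only regions alone numbered 848, with vehicle-only regions alone 4555, and with both 905. Germline genes had a vehicle-only region in 2 of 22 cases (6.5 expected, percentile 1). Wnt, Notch and progenitor genes had one in 16 of 30 cases (10.4 expected, percentile 98.95). That percentile was 73.3 with every list cut to 2552 peaks and 74.3 near gene ends. Club genes had a vehicle-only region in 9 of 24 cases (5.11 expected, percentile 97.4), among them Scgb1a1, Cyp2f2, Pigr and the mucin gene Muc5b. Inside the central 95% lay both region sets of the H3K9 list (3 G9ai-only and 7 vehicle-only of 25), the imprinted list (1 and 7 of 21), the interferon list (1 and 5 of 23) and the pan-epithelial list (4 and 7 of 22). So did the bivalent, cell-cycle, housekeeping, sort-marker, endothelial, immune, mesenchymal, mesothelial and neuroendocrine lists. Counted only near gene ends, the multiciliated list lay at percentile 41.9 in vehicle-only regions and the alveolar type 1 list at 99.7. Among genes with a region in either arm, the G9ai side held 3 of 6 basal genes (percentile 98.1) and 3 of 6 immune genes (percentile 97.9), the 2 combinations above the central range in 39 over both populations. Over all 3 populations, with arm labels exchanged within a population, the mean log2 ratio of list lengths was -0.59 (exact permutation p = 0.222, 54 arrangements, two-sided).

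Of the genes named beforehand, Epcam, Ly6a (Sca-1) and Cd24a, the positive markers of the sort, and Ager, an alveolar type 1 gene, had no region in any of the 6 sets. Scgb1a1 had a G9ai-only region in CD24low and a vehicle-only region in CD24high, which overlapped each other. Foxj1 had a vehicle-only region in CD24neg, a G9ai-only region in CD24low and a vehicle-only region in CD24high; the first 2 overlapped. Pecam1 had 1 vehicle-only region in CD24neg and 1 in CD24high beside the 4 of CD24low. Ptprc (CD45), Trp63 and Ehmt1, the partner of G9a, each had 1 vehicle-only region in CD24neg and none elsewhere in these sets.

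**Figure D3:**
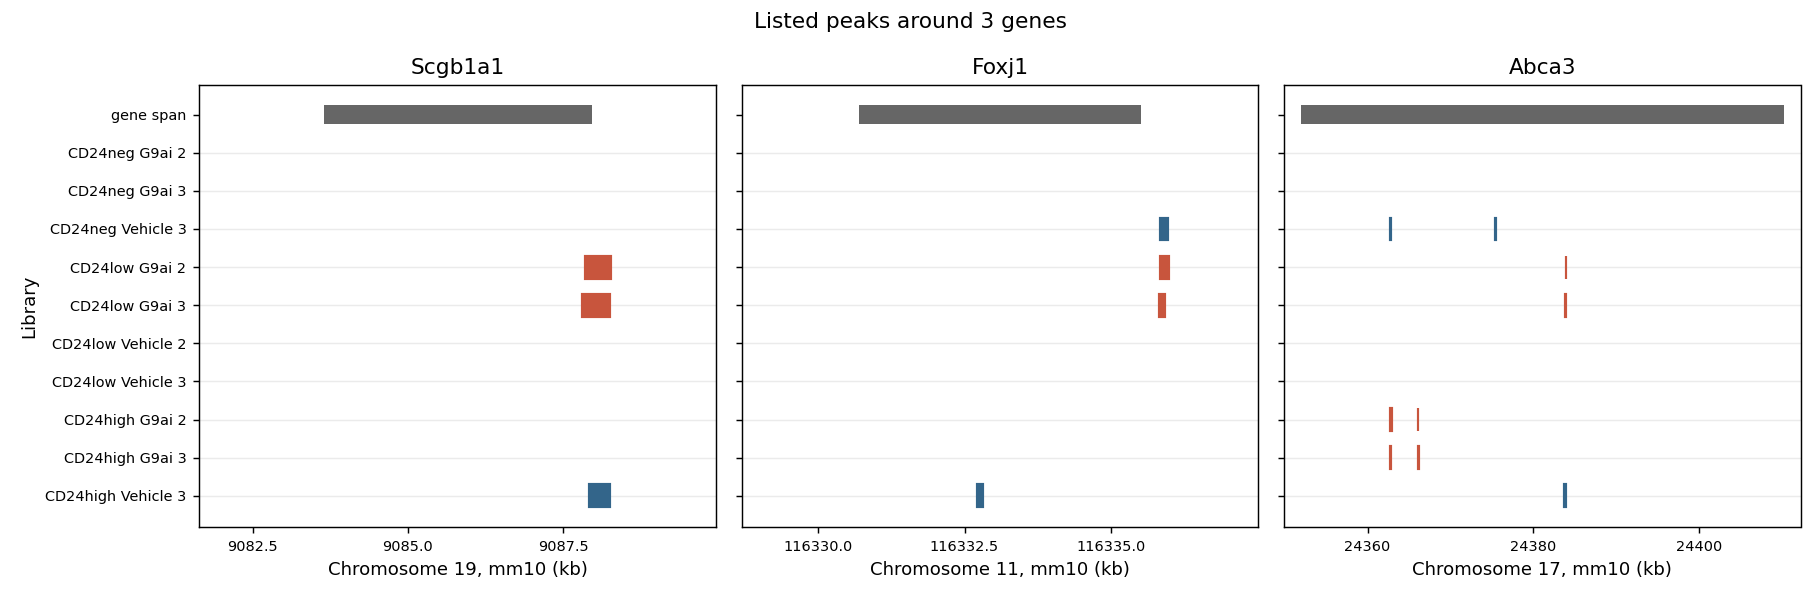
Listed peaks of the 10 libraries around Scgb1a1, Foxj1 and Abca3 (position in kb on mm10; grey bar, gene span; red G9ai, blue vehicle). At Scgb1a1 both CD24low G9ai libraries and the CD24high vehicle library list a peak at the same place, 9087796 to 9088263 and 9087916 to 9088246 on chromosome 19.

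Within the G9ai arm, where each population had 2 libraries, the question was which listed regions differed between populations. Every list had already been selected against the vehicle arm, and only G9ai lists were compared. A region found in 1 population alone may thus be open in the others, with vehicle or in both arms. Among the sites named below, those of Aqp3 and Thbs1 in CD24high and Vwf in CD24neg were vehicle-only in CD24low. Those of Scgb1a1, Tek and Ifit3 in CD24low were vehicle-only in CD24high. CD24low had 6458 regions absent from the other G9ai lists, CD24neg 3539 and CD24high 2324, of 13477 merged regions. Of the merged regions, 866 (6.43%) were seen in more than 1 population. The leading list genes found in CD24neg alone were Sox2, Vwf (von Willebrand factor, of endothelial cells), Hydin, Uhrf1, Ecscr, Acoxl, Spag16, Rac2, Reep5 and Axin2 (a Wnt target). In CD24low alone they were Pecam1, Scgb1a1, Pax6, Pigr, Cdhr3, Tek, Ifit3, Tfrc (the transferrin receptor), Ccnb1 and Rtkn2. In CD24high alone they were B2m, Cd79a, Gprc5a, Ifi35, Klf5, Dnah5, Aqp3, Thbs1, Cxcl15 and E2f1.

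Outside the lists, Riok3, Dcp1a, Senp2 and Sema3b led in CD24neg alone, Pdcl3, Hey2, Fuca2, Usp53 and Cbfa2t2 in CD24low alone, and Arhgap24, Gm2a, Tiprl, Supt4a and Tgfbr1 in CD24high alone. Basal genes were the list with the lowest p: 4 of the 6 with a region were found in CD24high alone (0.945 expected, odds ratio 10.7, Fisher exact p = 0.00702, adjusted p = 0.702). Club genes were found in CD24low alone in 6 of 11 cases (4.37 expected, Fisher exact p = 0.363). With equal list lengths CD24low had 1316 and CD24neg 1783 population-specific regions, and CD24high 2464; the longer the list, the more the cut removes, so these numbers give no order of the populations. Within vehicle, where CD24neg and CD24high had 1 library each, the numbers were 11302 for CD24high, 7339 for CD24neg and 1901 for CD24low, of 22477 merged regions.

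Regions that a pair of populations shared kept a common direction at most weakly, and only CD24neg with CD24high had an interval above 1, which held 1 in the higher-scoring 50% of peaks (0.659 to 2.48) and with equal list lengths (0.728 to 1.99). Of the 7172 CD24low G9ai-only regions, 980 (13.7%, Wilson interval 12.9% to 14.5%) overlapped a vehicle-only region of CD24high and 303 (4.22%, 3.78% to 4.72%) a G9ai-only one. Of the 2500 CD24low vehicle-only regions, 412 (16.5%, 15.1% to 18%) overlapped a vehicle-only region of CD24high and 100 (4%, 3.30% to 4.84%) a G9ai-only one. CD24high had 12880 vehicle-only and 2675 G9ai-only regions to overlap, so these shares alone do not show a change of direction. The odds ratio for sharing the direction was 1.27 (95% interval 0.983 to 1.66) for CD24low with CD24high, 1.10 (0.867 to 1.41) for CD24neg with CD24low, and 1.35 (1.07 to 1.69) for CD24neg with CD24high. This comparison was added after the data were seen, and its intervals cover counting error only.

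**Figure D4:**
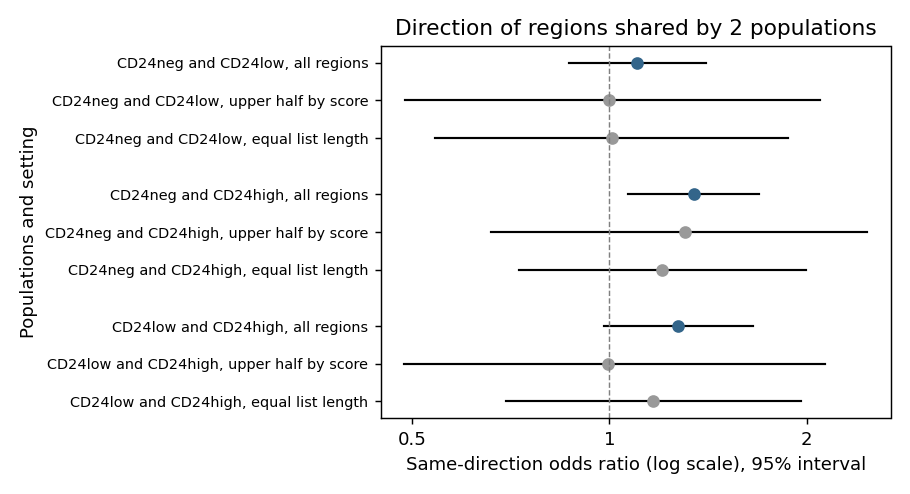
Odds ratio (log scale) for a region shared by a pair of populations having the same direction in both, with its 95% interval (counting error only), over all regions (blue) and under 2 alternatives (grey). Over all regions the values were 1.10, 1.35 and 1.27; under the alternatives every interval held 1.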

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

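The tests in this part were chosen after the list lengths had been seen. The ratio of list lengths, G9ai over vehicle, differed in direction between populations: 2.88 in CD24low, 0.469 in CD24neg and 0.216 in CD24high. Every library moved in the direction of its population. Replicate lists matched each other as deposited, and CD24neg and CD24high had 1 vehicle list each, so this is no independent check. The difference between populations was not tested.

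More peaks called in the arm with the longer list is a candidate explanation. In 3 of 3 populations every library of the arm with the longer list had the higher peak number, as that explanation requires, by as little as 634 in CD24neg (85201 against 84567). In CD24neg the mean peak numbers differed by 3277, less than the 4709 peaks by which the lists differed, so called peaks alone may not supply the excess there; these numbers are lower bounds. Fewer libraries behind the single vehicle lists could also lengthen them. Their lowest share of repeated lines was 1.23%, against 1.81% in the CD24low vehicle lists, and this leaves the number of libraries behind them open. A difference between the populations in their response to the inhibitor stays open and untested.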

How the results depend on the processing

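The comparison of directions between populations, its alternatives, the length-matched lists and the window at gene ends were added after the data were seen. There were 252 alternatives over 38 results, those of the list percentiles being given apart below. Of the others, 161 kept a main result. That meant a count within 1.5 times the main count, or a tested value with the same direction and side of its threshold, whatever its size. Every alternative that left out a library did so, but replicate lists overlapped almost fully as deposited. Leaving out a library could therefore change little, and it does not show agreement between mice. A further 25 moved a count beyond that factor or an untested value beyond the spread between replicates, 2 reversed a value and 2 ended a call. The cause was not tested unless stated.

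Taking the higher-scoring 50% of each list lowered region counts by construction: 1202 G9ai-only and 4393 vehicle-only in CD24neg, 2190 and 698 in CD24low, 825 and 6434 in CD24high, and within G9ai 1094, 2040 and 741 population-specific regions in CD24neg, CD24low and CD24high. With equal list lengths, a cut that by construction removes more from longer lists, vehicle-only regions numbered 4095 in CD24neg and 2773 in CD24high, G9ai-only regions 1243 in CD24low, and population-specific regions 1783 in CD24neg and 1316 in CD24low. Genes on the vehicle side were then 1610 in CD24neg and 1308 in CD24high, on the G9ai side 593 in CD24low and 1392 in CD24high. Near gene ends alone, where the window is smaller, G9ai and vehicle sides held 726 and 1336 genes in CD24neg, 1250 and 606 in CD24low, and 1892 on the vehicle side in CD24high. By covered length the log2 ratio was -0.97 in CD24neg and -2.12 in CD24high.

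In the higher-scoring 50% the direction odds ratio was 0.999 for CD24neg with CD24low, 0.997 for CD24low with CD24high and 1.31 for CD24neg with CD24high, and with equal list lengths 1.2 for the last pair, whose interval held 1 in both cases. Near gene ends 3 list percentiles reversed: 36.6 (alveolar type 2) and 46.6 (basal) in CD24neg vehicle-only regions, and 41.9 (multiciliated) in CD24high vehicle-only regions; the club list of CD24low G9ai-only regions fell to 96.4 there. Of the other list percentiles under alternatives 38 stayed outside the central range and 21, the club value included, did not.

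With the replicate block the CD24low log2 ratio was 1.53 (exact sign-flip p = 0.5, the smallest that 2 pairs allow). Over all populations, only replicate numbers present in both arms were kept, and labels were exchanged within a population, not within a replicate number. The mean log2 ratio was then -0.59 (exact permutation p = 0.583). Equal numbers in the 2 arms are different mice. Other settings chosen beforehand for motif content, promoters at transcription start sites, and exons and introns were not run. The lists carry no read depth, so the depth behind a missing peak is unknown.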

Other observations

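The tests in this part were chosen after the results were seen, except the reassignment of list genes, whose prediction was written before it was run. Regions that were G9ai-only in all 3 populations numbered 22, and 18 of them lay in or near a gene: they included Runx1, a transcription factor gene (92698751 to 92698902 on chromosome 16), Tnc (tenascin C), Uba1 (the main ubiquitin-activating enzyme), Pla2g6, Rbm47, Celf2 and Fat3. Regions that were vehicle-only in all 3 numbered 62, of which 40 lay in or near a gene, among them the chromatin genes Kdm2a, Kat2a and Chd6, the cohesin loader gene Nipbl, Polr2a, the proteasome genes Psmd1 and Psmd11, and Dnali1, a ciliary dynein gene. These genes were picked from the full set after it was seen.

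Sites of list genes recurred between populations in both manners. Of 101 overlapping pairs of list-gene regions from different populations, 55 had the same direction and 46 the opposite one. A site can count in several pairs, and the share expected from the arm totals was not computed for them. For all shared regions that share ran from 38.2% (CD24low with CD24high) to 62.6% (CD24neg with CD24high). A site in Krt18 (102028998 to 102029076 on chromosome 15) was G9ai-only in CD24neg and CD24high, and sites in Notch1, Dnmt3a and Mcidas were G9ai-only in CD24neg and CD24low. The site of Aqp3, a water channel gene of basal cells, was vehicle-only in CD24neg and CD24low and G9ai-only in CD24high. A site inside Abca3 was vehicle-only in CD24neg (24362647 to 24362887 on chromosome 17) and G9ai-only in CD24high (24362696 to 24362918). Sites of Scgb1a1, Cyp2f2 and Wwtr1 were G9ai-only in CD24low and vehicle-only in CD24high. Many of the genes with the most regions were long ones: Rad51b held 12 and Mecom 9 G9ai-only regions in CD24low, Nav2 held 15 vehicle-only regions in CD24neg and Maml3 16 in CD24high. Among CD24low vehicle-only regions, the shorter genes Adora1 (36.2 kb) and Cxxc5 (32.3 kb) held 3 each. Few regions sat next to a region of the opposite arm: within 500 bp lay 3.79% of the G9ai-only regions in CD24neg, 1.25% in CD24low and 5.20% in CD24high.

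Some gene lists held more treatment-specific regions than genes of the same length: 12 of 120 list and set combinations lay above the central 95% of random lists and 3 below it. The nominal number is 3 in each tail, which overstates the lower one, since a count of 0 often lay inside the range. Of the 12 above, the Wnt, Notch and progenitor list gave 4 and lung epithelial lists the other 8, while 13 lists, endothelial, immune and mesenchymal among them, gave none. The random lists were drawn from all 21883 protein-coding genes, matched on length alone and not on whether a gene is open in these cells. The excess thus does not show an effect of treatment: in CD24neg the Wnt, Notch and progenitor list exceeded the range in both region sets (percentiles 99.81 and 99.99). Against genes with a region, 0 of 100 Fisher exact tests had an adjusted p under 0.05. Chance over many lists is argued against by reassigning list genes within length bins: none of 1000 reassignments gave 12 combinations (highest 9, median 2), a share of 0.0999%, the smallest they can give. Whether the club regions follow the treatment or the population cannot be told apart: 77.8% of 18 club-linked CD24low regions were G9ai-only (exact interval 52.4% to 93.6%), which holds the 73.1% of all gene-linked regions. That interval counts regions of the same gene as independent and may be too narrow. No test against gene expression was made.

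Regions shared between populations kept their direction little more often than independent labels would: 46.4% against 45.5% for CD24neg with CD24low, 64.6% against 62.6% for CD24neg with CD24high, and 39.8% against 38.2% for CD24low with CD24high. For the lists as they stand, agreement in direction was low. Cohen's kappa reached at most 0.263, by its upper bound, of the highest kappa that the arm totals allow (0.412, 0.701 and 0.207 for those pairs). An effect of the inhibitor common to the populations at most shared regions was predicted to give a higher share, which the listed directions did not reach. Weak peaks that cross the calling threshold by chance could produce such values even with a common effect, so kappa cannot decide on that effect. Higher-scoring regions would then share direction only if a common effect were also present, so the test cannot decide on weak peaks alone. Among the higher-scoring 50% of peaks, 0 of 3 pairs had an odds ratio above 1 by its interval. Those intervals are also wide (to 2.10 for CD24neg with CD24low), so weak peaks stay open as an explanation. A response to the inhibitor that differs between populations stays open as well and was not tested.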
